A study of Homo sapiens with 4 samples.

How the data were processed

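The series holds ChIP-seq of ERRα in MDA-MB-231 cells, with 2 ERRα ChIP replicates and 2 inputs. Per the labels, cells were fixed with 1% formaldehyde and sonicated, chromatin of 2500000 cells was precipitated with 5 µg of an ERRα antibody, and libraries were sequenced as paired reads of 81 bp. The labels' read numbers are printed without an exponent sign and were read as 29000000 for ERRα and 10000000 for input libraries. Per the series' design text, the ChIP replicates came from 2 cell culture samples. The deposited files are a peak list for each ChIP replicate and a list of peaks matched between the replicates. Read counts per peak and per library were not used here, so no interval covers read depth.

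The submitters' processing notes name the genome build hg38 and the tools Trim Galore 0.6.5, Bowtie2 2.3.5, Picard, SAMtools, MACS2 2.2.6 and deepTools. Their settings are not given in the sources used here. The peak lists have the narrowPeak layout of MACS2, and each deposited list was called for a single replicate against the inputs. The fold enrichment of each peak is the authors' ratio of ChIP signal to the local input background at the summit. The −log10 p and −log10 q of each peak were also deposited by the authors, and the smallest −log10 q was 1.35 in replicate 1 and 1.37 in replicate 2. The deposited peak score was 10 times the −log10 q, truncated to whole numbers. The list of matched peaks has the 20 columns of IDR output, and its deposited score, which grows as the irreproducible discovery rate falls, ran from 154 to 1000. That list was therefore not filtered on IDR. Each matched peak's own value is the sum of the fold enrichments of both replicates. For 45 matched peaks in replicate 2 and 55 in replicate 1 the value was the sum over several peaks of that replicate, equal within 0.001, and for all others it was that of a peak with the same interval. These values were used to describe, rank and filter peaks, and the folds printed are means of the 2 replicates with their SD. With n = 2, an SD is itself imprecise. Inputs enter these values through the fold enrichment, and no separate input value per peak was used.

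Peaks on chromosomes 1 to 22, X and Y were analysed, and those on patch, alternate and unplaced contigs (371 in replicate 1, 358 in replicate 2 and 272 in the matched list) were counted apart. The reproducible set was the matched peaks with an IDR score of at least 540, which is an IDR of 0.05. Gene positions came from a RefSeq gene table of assembly GRCh38.p14, the same build as hg38, which gives the start and end of each gene but no strand. The planned distance to a transcription start site was replaced by the distance to either end of a gene, so a gene was called bound if a reproducible summit lay within 1 kb of its lower or upper coordinate. Of the 900 bound genes, 25 gene loci had summits at both ends. Of the 768 summits at gene ends, 632 were near 1 gene and 136 near 2 or more, which are then all called bound. Such sharing is mentioned for some of the named genes, not for all. No genome sequence was used here. Planned tests of the ERR response element, of a panel of motifs and of short words in the sequence under the summits were therefore not run (5 planned tests), nor was a background matched on CpG content.

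Overlap of the replicates was counted from 1 bp and compared with 1000 random placements of the same intervals on the same chromosomes (100 placements for 50% reciprocal overlap), with a one-sided permutation p. Chromosome ends were taken as the furthest gene or peak end. No stretch in between, such as an assembly gap where no peak can be called, was left out of the placements. The share at gene ends was tested in the same way, and the shares inside and outside genes were set beside the means of 200 placements. Shares have exact Clopper-Pearson 95% intervals. These intervals and all p-values cover positions or genes in these peak lists, not further cell cultures, since there are 2 ChIP libraries, and neighbouring peaks and genes are not independent.

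The 28 gene lists, with 820 entries that were all found in the gene table, were fixed before the data were examined. Members of each list were compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted by the Benjamini-Hochberg method over the 28 lists. Genes named in the text were set by a rule fixed at the same time, except those said to be named after their values had been seen. The rule takes ESRRA, the 10 strongest reproducible peaks with the nearest protein-coding gene, all 24 known ERRα targets, and the 4 bound members with the highest fold of every other list with an adjusted p under 0.05. The values of an item that this rule names are not reported here. Alternatives were windows of 500 bp and 5 kb, an IDR of 0.01 (score of at least 830), each replicate's own list in place of the matched one, a −log10 q of at least 5, overlap of 50% of both peaks or summits within 100 bp, and placement within 100 kb. Alternatives chosen after seeing the data were all matched peaks for the tests on genes, the share at gene ends with placement within 100 kb, peaks without chromosomes X and Y, and 10000 draws of genes matched on length and on protein-coding genes within 50 kb, in 5 bins each.

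The list test was tested on simulated data over 20037 genes. With 10 lists bound at 30% over a background of 4%, it recovered 91.6% of them in 100 simulations, with 11 false calls among 1283 lists that shared no gene with these. Each gene was drawn independently. These rates therefore do not cover lists with smaller shares bound, or neighbouring genes that share a summit. For the replicate overlap, 14072 simulated peaks with 5533 planted shared ones gave all 5533 back. The planted peaks were given the starts of replicate 2 peaks, so this result was fixed in advance. It checks the counting alone, and neither the sensitivity of the comparison nor its permutation p. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.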

Results

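Binding of the oestrogen-related receptor ERRα to the genome was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in MDA-MB-231, an established line of triple-negative, invasive human breast cancer cells. ERRα is an orphan nuclear receptor, best known as a regulator of genes for mitochondrial energy metabolism. The series holds 2 ERRα ChIP replicates and 2 input libraries of sonicated chromatin without immunoprecipitation, made from cell culture samples. Per the labels, ERRα libraries gave 29000000 reads and input libraries 10000000. The stated aim was to identify ERRα target genes, so the design implies a comparison of the replicates with each other, of the ERRα peaks with the rest of the genome, and of gene groups by the presence of a peak. Replicate 1 had 14072 peaks on chromosomes 1 to 22, X and Y, and replicate 2 had 12659, with a median width of 488 bp in each. The deposited list of matched peaks held 10059, of which 5070 passed an irreproducible discovery rate (IDR) of 0.05. These 5070 are called reproducible peaks here. They had a median width of 774 bp and covered 4.44 Mb.

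The strongest ERRα peak in both replicates lay beside ESRRA, the gene that encodes ERRα. Its fold enrichment over input was 544 in replicate 1 and 543 in replicate 2. The peak beside SLC25A6, a carrier that exchanges ADP and ATP across the inner mitochondrial membrane, came to 285 and 300. The peaks beside the ATP synthase genes ATP5MC3 (85.9 and 84.2) and ATP5F1B (60.6 and 65.3) were of similar height in both replicates, and so were those beside NDUFS7, a complex I subunit (61.9 and 54.9), and ACADM, an enzyme of fatty acid oxidation (20.9 and 17.3). All these peaks had passed IDR, which selects for agreement of the replicates, so their like heights are not separate evidence of it. Of the replicate 1 peaks, 10117 of 14072 (71.9%, 95% interval 71.1 to 72.6) overlapped a replicate 2 peak by at least 1 bp, and 10106 of 12659 replicate 2 peaks (79.8%, 79.1 to 80.5) overlapped a replicate 1 peak. Random placement of the replicate 1 peaks on their chromosomes gave 0.596% on average and 0.846% at most (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Placement within 100 kb of the true position gave 2.08% on average and 2.44% at most. Across the 10117 shared peaks, which are not independent replicates, Spearman's rho of fold enrichment was 0.849. Both replicate lists were called against the same 2 inputs, so their folds share a background. Its part in the overlap and in rho was not tested.

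Sharing depended on peak strength. Of 5 equal groups of replicate 1 peaks ordered by fold, the strongest, with folds of 12.4 and above, had 99.96% of peaks shared, and in the weakest, with folds up to 5.15, 37.7% were (95% interval 35.9 to 39.5). In replicate 2 the corresponding shares were 99.96% and 50.0%. The median fold of shared peaks was 8.58 in replicate 1 and 8.39 in replicate 2, against 5.33 and 5.26 for peaks found in that replicate alone. With all 10059 matched peaks in place of the 5070 that passed IDR, the peak set was larger by more than 1.5 times.

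**Figure D1:**
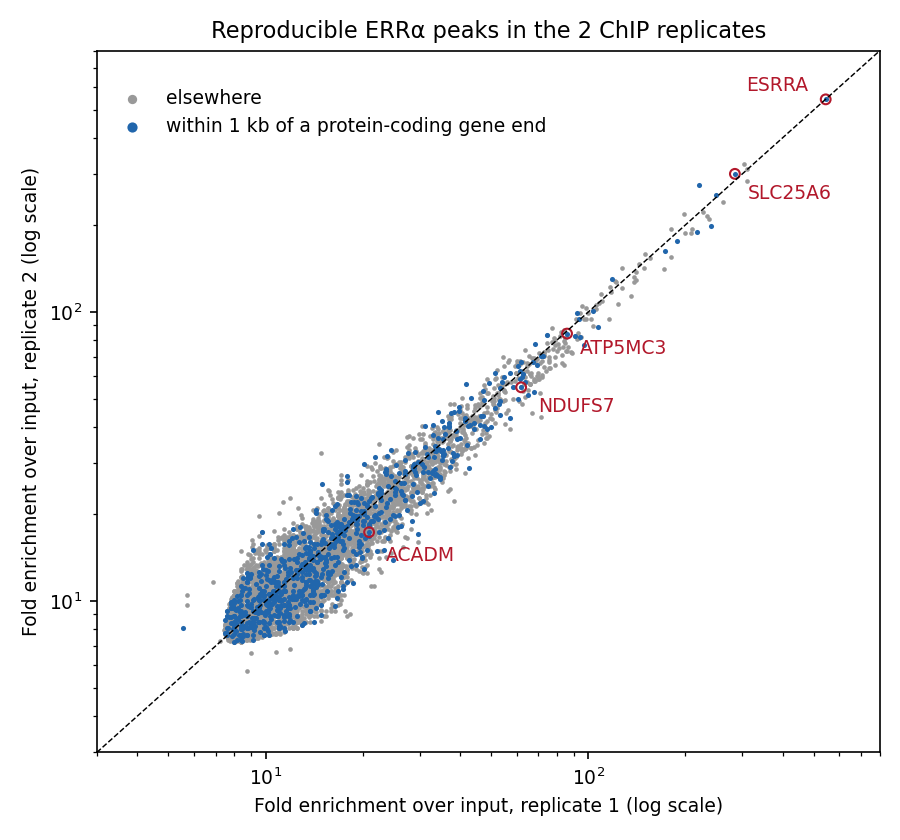
Fold enrichment over input of each of the 5070 reproducible ERRα peaks in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), with the dashed line marking equal values. Blue points are the 768 peaks with a summit within 1 kb of a protein-coding gene end, grey points are all others, and 5 named peaks are circled, with ESRRA at the top right at 544 and 543.

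At ESRRA, the peak spanned chromosome 11 from 64303981 to 64306377 (GRCh38), with its summit at 64304849. The summit lay 675 bp outside the lower-coordinate end of ESRRA and 79 bp outside the upper end of CATSPERZ, a neighbouring gene of a sperm ion channel complex. The mean fold was 544 ± 0.518 (SD, n = 2), which was 1.73 times that of the second strongest peak. Within 50 kb of ESRRA there were 5 reproducible summits in all, and the next strongest of these reached 24.6 ± 2.36 (SD, n = 2). Because the ESRRA summit is 675 bp from the gene, ESRRA is not counted as bound when the window is narrowed to 500 bp.

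**Figure D2:**
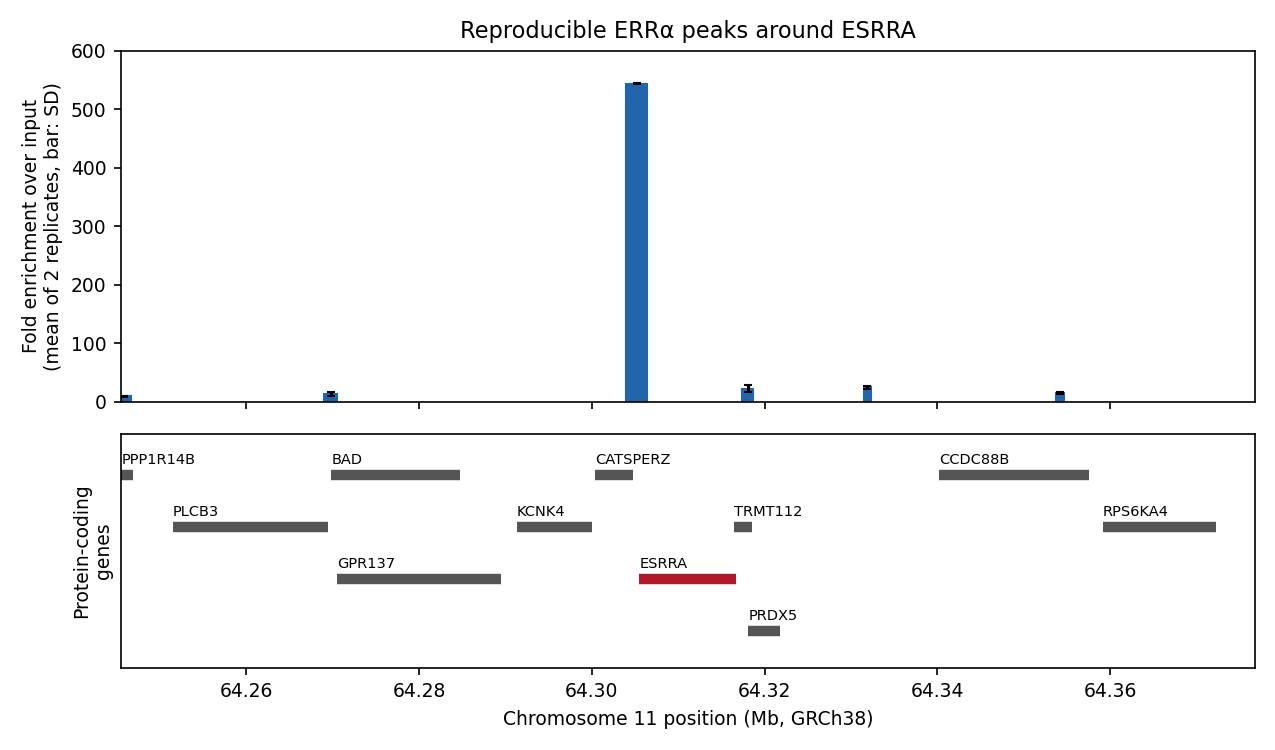
Reproducible ERRα peaks (upper panel, bars drawn at the peaks' width, height the mean fold enrichment over input of 2 replicates, error bars the SD) and protein-coding genes (lower panel, ESRRA in red) on chromosome 11, position in Mb on GRCh38. The peak between CATSPERZ and ESRRA reaches 544, and no other peak drawn exceeds 24.6.

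Among the 10 strongest peaks, 4 had a summit within 1 kb of a protein-coding gene end. Besides ESRRA, these were the peak at SLC25A6 (X, 1391207 to 1392962, mean fold 292 ± 11.1, SD, n = 2), the peak 215 bp from ITFG2, a gene of an amino acid sensing complex (chromosome 12, 2811858 to 2813184, 251 ± 3.92), and the peak at the adjoining ends of ACYP1 and ZC2HC1C (chromosome 14, 75068856 to 75069966, 247 ± 38.9). The other 6 lay away from gene ends. The second strongest, on chromosome 5 from 142361594 to 142364683, lay in the non-coding gene SPRY4-AS1, 37.9 kb from SPRY4, an inhibitor of growth factor signalling (314 ± 16). The third lay outside genes on chromosome 14 from 76955717 to 76957197, 68.0 kb from IRF2BPL (311 ± 0.890). Others were inside ERGIC1 (297 ± 18.7), a gene of transport between the endoplasmic reticulum and the Golgi, inside CRIM1 (250 ± 15.6), inside TMEM127 at 5.40 kb from its end (224 ± 12.3), and 30.1 kb from NKX2-5, a cardiac transcription factor (225 ± 3.72). The folds of the third and the second differed by less than the SD of the second.

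ERRα summits were found at the ends of protein-coding genes more often than randomly placed ones. Of the 5070 reproducible summits, 768 (15.1%, 95% interval 14.2 to 16.2) were within 1 kb of such an end, against 2.86% on average and 3.61% at most for random placements, a ratio of 5.29 (one-sided permutation p = 0.001, the smallest that 1000 placements can give). A further 2324 (45.8%) were inside a protein-coding gene away from its ends, against 41.8% at random, and 1322 (26.1%) were outside all genes, against 41.1%. The median of the mean folds was 13.4 at gene ends, 12.8 inside genes and 12.8 outside genes. All matched peaks, including those that failed IDR, were also split into 10 groups by the sum of both replicates' folds. In the weakest group, where no peak passed IDR, 19.8% of summits (95% interval 17.4 to 22.4) were at gene ends. In the strongest group 18.6% (16.2 to 21.1) were, and in the others 11.6% to 15.7%. The excess at gene ends was therefore not special to reproducible peaks. Start and end of a gene were not told apart, since the gene table used here gives no strand. When each peak was instead placed at random within 100 kb of its true position, the random share at gene ends was 4.90% and the ratio 3.09. The shares inside and outside genes were not repeated with this local placement. Their differences from random may in part come from chromosome stretches where no peak can be called.

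A reproducible summit within 1 kb of a gene end, called bound from here on, was found for 900 of 20037 protein-coding genes (4.49%). Of 24 genes known as ERRα targets from earlier work, 9 (37.5%, 95% interval 18.8 to 59.4) were bound, against 4.45% of all other genes (odds ratio 12.9, two-sided Fisher's exact test, p = 2.85e-06 adjusted over 28 gene lists). Besides ESRRA, the strongest was at ATP5F1B, the catalytic beta subunit of ATP synthase (mean fold 62.9 ± 3.27, SD, n = 2). IDH3A, a subunit of isocitrate dehydrogenase, reached 26.8 ± 1.36, and ENO1, a glycolytic enolase, 25 ± 6.82. ACADM (19.1 ± 2.55), the lactate dehydrogenase gene LDHB (17.1 ± 1.70), the mitochondrial fusion gene MFN2 (12.8 ± 3.36) and the cytochrome oxidase gene COX5B (12.4 ± 2.96) were also bound. Of the 24 known targets, 15 are also members of another of the 28 lists, and all 9 bound genes are among these. No target found in this list alone was bound. This result and those of the metabolic lists therefore share genes and are not separate evidence. In the lists of replicate 2 and replicate 1 alone, 13 and 14 of the 24 were bound, and the share over that of other genes was 4.95 and 4.81, against 8.42 for reproducible peaks.

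The other 15 known targets were not bound. PDK4, a kinase that inhibits pyruvate dehydrogenase and a frequently used ERRα target in muscle and liver, was 885 kb from the nearest reproducible summit. The breast cancer genes ERBB2 and GRB7 were 286 and 267 kb away, TFF1, an oestrogen-induced gene, 656 kb, and NR0B2, a corepressor, 123 kb. LTF (326 kb), PERM1 (333 kb), GABPA (617 kb), SPP1 (2148 kb) and MAOB (2253 kb) were also far from any reproducible summit. VEGFA, WNT11 and NRIP1 each had a summit inside the gene but over 1 kb from its ends, and VEGFA and WNT11 are counted as bound with a window of 5 kb. CYCS, which encodes cytochrome c, and TNFAIP1 had a matched peak at an end that did not pass IDR 0.05. In a single replicate's own list, PDK4, PERM1 and GABPA had a summit at an end in replicate 1, and VEGFA and TFF1 in replicate 2.

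Mitochondrial genes were bound more often than other genes in all 7 mitochondrial lists tested. These lists cover energy metabolism, the mitochondrial ribosome, and mitochondrial import, dynamics and genome maintenance. Of complex I subunits and assembly factors, 16 of 50 (32.0%) were bound, led by NDUFS7 (mean fold 58.4 ± 4.99, SD, n = 2) and NDUFB5 (26.7 ± 6.94), followed by NDUFAF4 (26.1 ± 3.54) and NDUFB4 (24.2 ± 1.34). Of complexes II, III and IV with cytochrome c, 16 of 43 (37.2%) were bound, among them the cytochrome oxidase genes COX4I1 (60.5 ± 4.77), COX8A (53.1 ± 5.48) and COX10 (35.3 ± 3.82) and cytochrome c1, CYC1 (57.2 ± 3.23). ATP synthase and the adenine nucleotide carriers had 8 of 24 bound (33.3%), with SLC25A6 (292 ± 11.1), ATP5MC3 (85.1 ± 1.23), ATP5F1B and SLC25A5 (48.6 ± 6.62) the strongest. The adjusted p-values of these lists were 2.63e-09, 2.86e-10 and 2.49e-05 (two-sided Fisher's exact test over 28 lists).

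The citric acid cycle and pyruvate oxidation had 9 of 28 genes bound (32.1%, Fisher's exact adjusted p = 1.07e-05). These included OGDH (38.4 ± 5.27, SD, n = 2), which encodes a subunit of the oxoglutarate dehydrogenase complex, IDH3A and the pyruvate carrier gene MPC1 (23.2 ± 0.702). Fatty acid oxidation had 6 of 24 bound (25%, Fisher's exact adjusted p = 0.00169), with ACADM, CPT1A (14.5 ± 1.24), the enzyme that commits fatty acids to mitochondrial import, DECR1 (14.4 ± 1.26) and ECI1 (13 ± 2.16). Mitochondrial ribosome genes were bound in 18 of 74 cases (24.3%, Fisher's exact adjusted p = 2.21e-08), among them MRPS25 (41.9 ± 3.31), MRPL48 (34.0 ± 1.30) and MRPL12 (29.96 ± 2.82). MRPL47 (26.7 ± 6.94) shared its summit with its neighbour NDUFB5. Mitochondrial import, dynamics and genome maintenance had the highest share, 17 of 41 (41.5%, Fisher's exact adjusted p = 1.63e-11), with the chaperone genes HSPA9 (50.2 ± 4.20) and HSPD1 (23.6 ± 1.56) and the import genes TIMM8B (31.9 ± 0.454) and TIMM10 (26.7 ± 3.99). The HSPD1 summit was shared with HSPE1, its partner chaperone, and the TIMM8B summit with SDHD, a complex II subunit. In each replicate's own list, which holds weaker peaks, the share of all protein-coding genes bound was 10.99% in replicate 2 and 12.2% in replicate 1, and the list counts rose with it. In that order they were 30 and 35 for complex I, 24 and 26 for complexes II to IV, 18 and 18 for ATP synthase and carriers, 15 and 17 for the citric acid cycle, 10 and 10 for fatty acid oxidation, 33 and 34 for the mitochondrial ribosome, and 20 and 24 for import, dynamics and genome maintenance. At an IDR of 0.01 the ATP synthase list had 5 bound.

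Glycolysis and lactate genes were also bound more often than others, with 7 of 23 (30.4%, Fisher's exact adjusted p = 1.64e-04). The strongest were GAPDH (38.7 ± 2.43, SD, n = 2), PGAM1 (32.4 ± 1.37), the pyruvate kinase gene PKM (28.5 ± 6.85) and TPI1 (27.0 ± 2.24). With a 500 bp window 4 of the 23 were bound. Lysosome and autophagy genes had 5 of 28 bound (17.9%, Fisher's exact adjusted p = 0.021), among them the protease gene CTSA (30.8 ± 2.63), GABARAPL1 (15.6 ± 0.436), the proton pump gene ATP6V0D1 (14.4 ± 2.38) and BECN1 (9.69 ± 0.662). Of AP-1 and Hippo pathway genes, 4 of 21 were bound (19%, Fisher's exact adjusted p = 0.0334), namely FOSL1 (21.8 ± 5.38), an AP-1 subunit, AMOTL2 (20.2 ± 0.535), TEAD3 (11.1 ± 1.94) and CCN1 (11 ± 1.34). The FOSL1 summit was shared with its neighbour CCDC85B. Shared summits were also those of TPI1 (with USP5), CTSA (with SPATA25 and NEURL2) and ATP6V0D1 (with AGRP). Without strand, none of the 4 summits of the AP-1 and Hippo list can be placed at the start rather than the end of its gene. The share bound was 3.99 times that of other genes for the lysosome list and 4.26 times for the AP-1 list. Against genes matched on length and neighbouring genes these ratios were 3.40 and 4.18, and neither passed (permutation, adjusted p = 0.0672 for each). With a 500 bp window, where 2 and 3 members were bound, they were 2.53 and 5.08 (Fisher's exact adjusted p = 0.475 and 0.0572). The AP-1 list also missed the threshold with a 5 kb window (ratio 2.57, Fisher's exact adjusted p = 0.0924), in the list of replicate 2 alone (6 bound, 2.60, 0.0518) and with all matched peaks (2.69, 0.0774), and passed in that of replicate 1 alone (9 bound, 3.53, 0.0011) and at an IDR of 0.01 (0.0177). The lysosome list had 10 bound in each replicate's own list (Fisher's exact adjusted p = 0.0013 in replicate 2 and 0.0027 in replicate 1).

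The remaining 17 lists did not pass the same test. No gene was bound among 20 of cholesterol and fatty acid synthesis (95% interval up to 16.8%), 31 proteasome genes (up to 11.2%), 18 heat shock and unfolded protein response genes, or 18 each of liver, neuron and blood cell markers and olfactory receptors (up to 18.5% for each list of 18). Of 20 glutamine, serine and one-carbon genes, the aspartate aminotransferase genes GOT1 (36.9 ± 1.31, SD, n = 2) and GOT2 (17.1 ± 4.01) were bound. Focal adhesion and actin genes had 4 of 38 bound (10.5%, Fisher's exact adjusted p = 0.209), namely VCL, which encodes vinculin (55.8 ± 2.32), LIMK1 (11.5 ± 0.920), PFN1 (9.49 ± 0.108) and PXN (8.67 ± 0.661). With a 5 kb window, 8 of the 38 were bound, 2.27 times the share of other genes (Fisher's exact adjusted p = 0.0542). CCN1 was the bound member of 29 invasion and extracellular matrix genes, and the cyclin gene CCNE1 (60.0 ± 2.25) that of 30 cell cycle genes. Of 36 nuclear receptors and coregulators, ESRRA, NCOA1 (15.8 ± 0.348) and the clock gene NR1D1 (15 ± 3.92) were bound, and NR1D1 was the bound member of the 20 circadian genes. EGLN1 (15.2 ± 2.15), an oxygen sensor, was bound among 18 hypoxia genes. Luminal breast markers had ELF3 (10.6 ± 0.128) and SPDEF (8.17 ± 0.371) bound of 18, and basal and mesenchymal markers had FOSL1 of 18. These counts are for reproducible summits within 1 kb of a protein-coding gene end, which are 768 of the 5070. A gene with summits only farther from its ends counts as not bound, so these lists are not shown to lack ERRα peaks. In the lists of replicate 2 and replicate 1 alone, in that order, 4 and 2 cholesterol, 3 and 4 proteasome, 4 and 5 heat shock, 7 and 6 focal adhesion, 7 and 9 nuclear receptor, 6 and 6 invasion and 3 and 5 cell cycle genes were bound. The other lists here, apart from the neuron, blood cell and olfactory lists, also had more members bound there than printed above, and only the cytosolic ribosomal list passed the test in either. Members of the lists in this paragraph were named after their values had been seen.

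**Figure D3:**
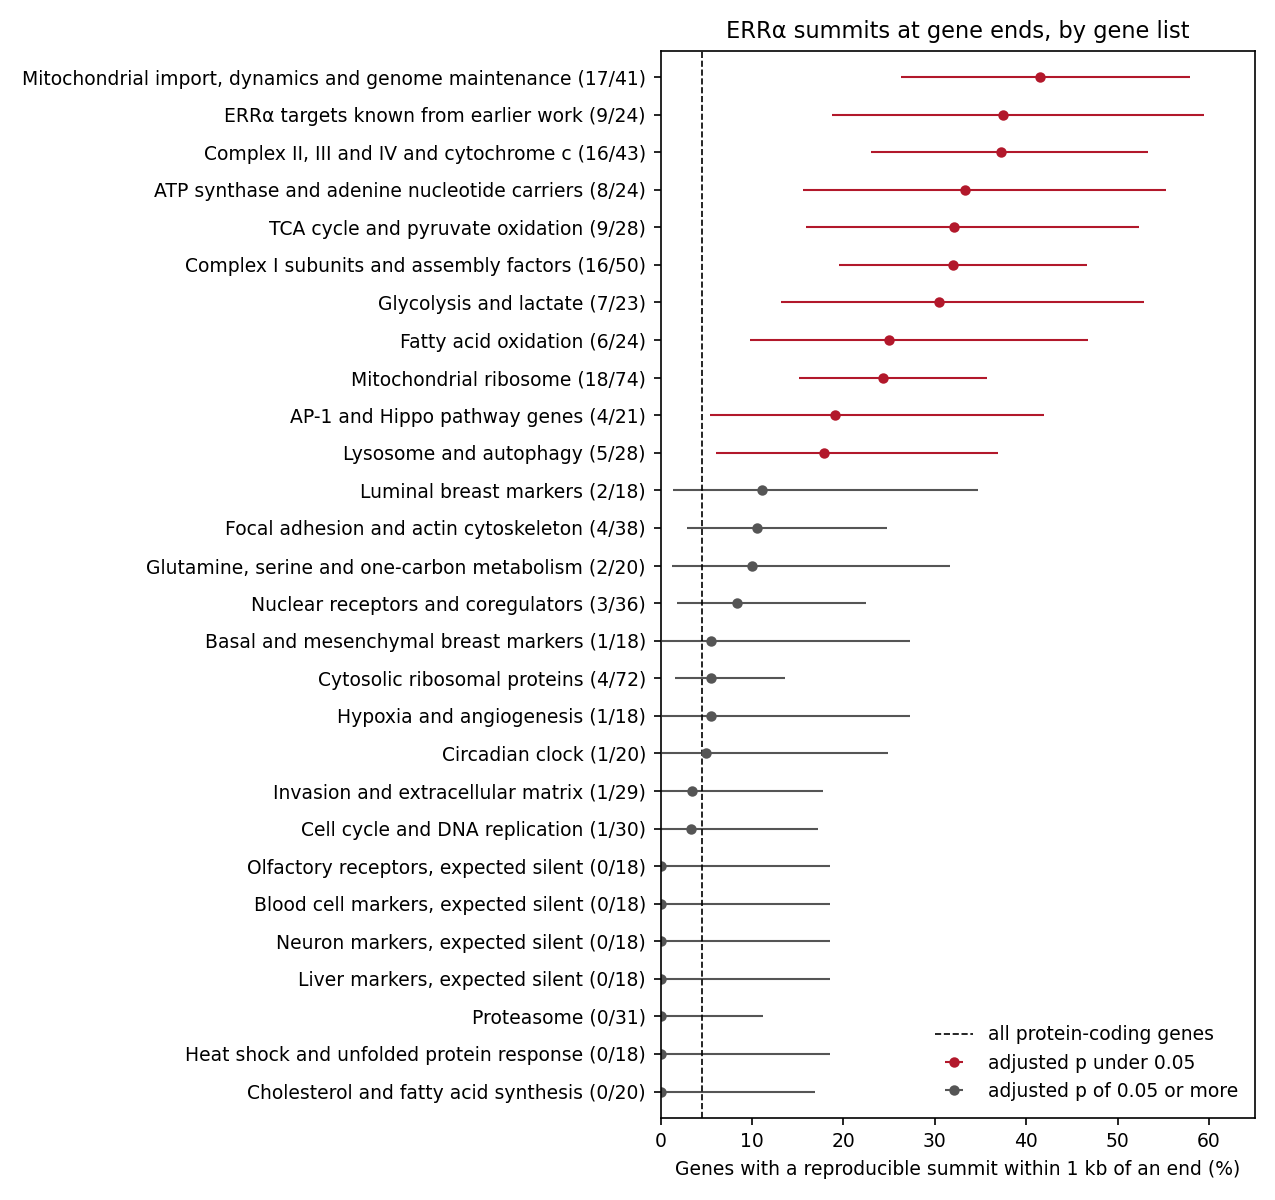
Share of genes in each of 28 lists with a reproducible ERRα summit within 1 kb of a gene end (x axis, percent), with bound and total members beside each list name and exact 95% binomial intervals as bars. The 11 lists in red passed an adjusted p of 0.05, and the dashed line marks the 4.49% of all protein-coding genes.

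The respiratory chain was compared with the cytosolic ribosome, since genes of both groups are active in dividing cells. Of 117 respiratory chain genes, which are those of complex I, of complexes II to IV with cytochrome c, and of ATP synthase with its carriers, 40 were bound (34.2%, 95% interval 25.7 to 43.5). Of 72 cytosolic ribosomal protein genes, 4 were bound (5.56%, 1.53 to 13.6), namely RPL26 (34.9 ± 4.65, SD, n = 2), RPL4 (30.3 ± 3.49), RPL21 (13.5 ± 1.95) and RPS14 (8.52 ± 0.573), which were named after their values had been seen. The odds ratio was 8.83 (two-sided Fisher's exact p = 2.30e-06). It was smaller in peak sets that hold weaker peaks, where more genes of both groups were bound. In the list of replicate 2 alone it was 3.64, with 61.5% of respiratory chain genes and 30.6% of ribosomal genes bound. In that of replicate 1 alone it was 3.46 (67.5% and 37.5%), and over all matched peaks 4.31 (60.7% and 26.4%).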

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

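On patch and alternate contigs, which no comparison above uses, 136 of 264 matched peaks passed IDR 0.05. On the standard chromosomes 5070 of 10059 (50.4%) passed, a like share. The contigs were flagged because any count above 3 was to be looked at, not because fewer peaks were predicted. The 264 peaks lay on 122 contigs, and the 136 had a median summed fold of 25.1 and a highest of 247, beside a median of 25.9 for the reproducible set on the standard chromosomes. Many such contigs repeat parts of the standard chromosomes, so a locus can be held in more than a single place.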

How the results depend on the processing

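The alternatives with all matched peaks for tests on genes, with genes matched on length and neighbours, without chromosomes X and Y, and with local placement for gene ends were chosen after seeing the data. No result past its test changed direction under any alternative run. The reproducible set of 5070 peaks grew to 10059 when all matched peaks were taken, and rho of fold enrichment rose from 0.849 to 0.875 over peaks with summits within 100 bp. The share at gene ends stayed above random in 8 of 8 alternatives, from 9.88% with a 500 bp window to 30.7% with 5 kb, and was 15.2% and 15.3% in each replicate's own list. Overlap of replicate 1 with replicate 2 lay between 59.9% and 75.2%. The number of lists bound more often ran from 9 to 12 around 11, and came to 11 without replicate 1 and 12 without replicate 2. No list passed as bound less often. In the main setting, with 4.49% of all genes bound, the lists are too small to show this. There 0 of 31 proteasome genes bound gave an unadjusted Fisher's exact p of 0.401. The changed calls were those of the lysosome and AP-1 lists, and of cytosolic ribosomal proteins, which passed without replicate 1 (adjusted p = 1.93e-05), without replicate 2 (1.33e-07) and with all matched peaks (3.82e-05), all by Fisher's exact test. The cause was not tested beyond the values given under other observations. The respiratory chain exceeded the cytosolic ribosome in 6 of 6 alternatives, with odds ratios from 3.46 to 11.1. Counts of summits at named genes were the same as in the main setting in 340 cases and differed in 20.

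No paired analysis was possible because the peak lists were called against the inputs and no test compares ChIP with input libraries here. Overlap and rank agreement need both replicates, so neither was computed without either. The 5 planned tests that need a genome sequence, and the CpG-matched background, were not run.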

Other observations

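Of the bound genes outside the 28 lists, the 25 with the highest mean folds were taken after these had been seen, and those with provisional symbols and those at the peaks already described are left out. FRAT2, a regulator of Wnt signalling, reached 219 ± 30.1 (SD, n = 2), TKT, the transketolase of the pentose phosphate pathway, 203 ± 19.8, PPIA, which encodes cyclophilin A, 182 ± 9.32, and NRSN2 168 ± 7.43. Next came AIFM2, which protects cells from ferroptosis (125 ± 8.29), the mitochondrial phosphatase gene PPTC7 (102 ± 2.01) and TWF2, an actin-binding protein gene (95.5 ± 4.71). A summit shared by TAPBPL and the immune receptor gene CD27 had 93.9 ± 0.738, and that shared by NOP16 and HIGD2A, which takes part in respiratory complex assembly, 87.0 ± 14.3. The mitochondrial chaperone gene TRAP1 had 86.7 ± 6.06, FRMD5 78.9 ± 6.22, MIDN 72.9 ± 6.26 and TRIAP1 71.6 ± 1.5. SFXN4, a mitochondrial protein gene, had 70.8 ± 0.826 and the autophagy protease gene ATG4D 67.5 ± 2.54. No shared function of these genes was tested.

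Gene families defined by a shared symbol stem, with at least 10 members each, were tested in the same way as the lists, a test chosen after the data had been seen. Of 282 families, 4 were bound more often than other genes and 1 less often (two-sided Fisher's exact test, adjusted over the 282). The higher ones were COX with 10 of 26 bound (adjusted p = 2.47e-05), MRPL with 12 of 49 (1.17e-04), TIMM with 7 of 15 (1.19e-04) and NDUFB with 5 of 11 (0.00376), all by the same exact test. Apart from COX4I2, every bound gene of these 4 families is also a member of the mitochondrial lists. The 4 results are therefore not separate evidence from those lists. The olfactory receptor family was lower, with OR2AJ1 the 1 bound gene of 392 (Fisher's exact adjusted p = 6.00e-05). MRPS genes did not pass, with 6 of 28 bound (Fisher's exact adjusted p = 0.0611). The number of reproducible peaks per 100 protein-coding genes ran from 46.9 on chromosome 20 (95% interval 41.3 to 53.1) to 13.8 on chromosome 21 and 7.19 on X (5.50 to 9.24). Per Mb the order differed, with chromosome 19 highest at 4.49 and Y lowest at 0.245. The Y chromosome had 14 reproducible peaks, which are counted in the 5070. All of them lay in a single block of 92.1 kb, and none was within 1 kb of a protein-coding gene end. Whether they reflect ERRα binding was not tested.

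In the 2 paragraphs that follow, the comparisons with other housekeeping genes, with and without the lysosome and autophagy list, were chosen after the result had been seen. Of the 284 genes in the mitochondrial lists, 90 (31.7%) were bound. Short genes in gene-dense places do not account for this, since genes matched on length and neighbours were bound in 4.93% of cases on average and 12% at most, a ratio of 6.42 (two-sided permutation p = 0.0002, the smallest that 10000 draws can give). Binding at active housekeeping genes in general is argued against by all 4 housekeeping lists, of which 10 of 161 genes (6.21%) were bound (odds ratio 7.01, Fisher's exact p = 5.76e-11), or 5 of 133 without the lysosome and autophagy list (odds ratio 11.9, Fisher's exact p = 3.20e-12), and a few broad peaks shared by neighbours by the 86 distinct summits of the 90 genes. Against the lysosome and autophagy list alone, with 5 of 28 bound, a difference was not shown (odds ratio 2.13, Fisher's exact p = 0.195), so binding at some other active genes to a like degree stays open. Over all matched peaks these comparisons were not run. There 26.4% of ribosomal, 32.1% of lysosome, 6.45% of proteasome and 6.67% of cell cycle genes were bound. In that setting the mitochondrial lists had 33.3% to 75% bound, against 8.85% of all protein-coding genes. The level of transcription and the motif content of these sites were not tested, and no biological explanation was tested because the design holds a single cell line without a contrast.

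Ribosomal protein genes appeared among the weaker peaks. Of 68 not bound in the reproducible set, 15 (22.1%) had a matched peak that failed IDR 0.05 at an end, against 4.57% of all such genes, and genes matched on length and neighbours gained 5.07% on average and 17.6% at most, a ratio of 4.35 (two-sided permutation p = 0.0002, the smallest that 10000 draws can give), which argues against gene length and density as the whole cause. The other housekeeping lists gained 7 of 83 (odds ratio 3.07, Fisher's exact p = 0.0215), or 3 of 60 without the lysosome and autophagy list (odds ratio 5.38, Fisher's exact p = 0.00929), which argues against an equal gain at all active housekeeping genes. The lysosome and autophagy list alone gained 4 of 23 (17.4%), and a difference from it was not shown (odds ratio 1.34, Fisher's exact p = 0.772). From the reproducible set to all matched peaks, bound respiratory chain genes rose from 40 to 71 of 117, and bound ribosomal genes from 4 to 19 of 72. A gain among weaker peaks was therefore not special to ribosomal genes. A candidate explanation that stays open is background signal at very highly transcribed genes, for which no expression values were used here, and no biological explanation was tested.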
